A study of Mus musculus with 36 samples.

How the data were processed

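RNA was extracted from mouse embryonic stem cells and libraries were made with a SMARTer mRNA-seq kit, per the labels' protocols, which also describe serum replacement medium with LIF and, typically, gelatin-coated plates with irradiated mouse fibroblast feeders. Per the submitters' processing notes the tools were FastQC 0.11.7, HISAT2 2.1.0, featureCounts 2.0.1 and DESeq2 (version not given in the sources used here), with the mm10 genome; the strand setting, annotation release and filters are not given in the sources used here. The authors deposited 1 table of raw read counts per gene with gene ID, name and type, per the file headers, and whole numbers for 36 libraries. Each column carried the title of 1 library, and groups (3 treatments by 4 days, 3 libraries each) came from the labels. The table held 55335 genes, of which 54587 (98.6%) matched a gene of the GENCODE M21 annotation on GRCm38, used for positions, transcript length and GC content, as did 17020 (97.8%) of the 17394 genes tested. There were 107 symbols shared by several gene IDs, which were kept as separate genes.

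Everything from here on was computed from those counts. Genes were kept with edgeR's filterByExpr on the 12 groups (minimum count 10, minimum total 15), which left 17394. Scaling was by TMM, and CPM used the scaled totals. All 36 libraries entered 1 fit of 12 groups, since 3 libraries estimate the spread poorly alone, with edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment over the genes tested, two-sided, called at an adjusted p under 0.05. The common biological coefficient of variation was 3.86% (dispersion 0.00149). Comparisons were each treatment against DMSO of the same day, BPK25 against IAA of the same day, and DMSO at days 2, 4 and 6 against day 0; for each treatment a joint test asked whether its effect differed between days. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

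Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists within a comparison, and again with an estimated correlation and with fry. The lists cover NuRD, CTCF and cohesin, pluripotency states, lineages, stress and metabolic programs, and fibroblast feeder cells; the feeder list shares Acta2 and Tagln with smooth muscle and its collagens are also made by differentiating cells. Named genes were the 5 highest and 5 lowest log2 fold changes of a comparison (10 and 10 for DMSO day 6 against day 0) among genes with a mean of at least 5 CPM in 1 group, no overlap between the libraries of the groups and a symbol that is not a predicted or clone name, the 5 smallest p-values per joint test, up to 4 members of each list described, and always Ctcf and NuRD subunits. Genes that met the rule and lists that were called are not all described. With 3 libraries against 3, groups fail to overlap for 10% of unchanged genes. Tspan18, Ift22 and Hist1h2aj met the rule but lost their call without at least 1 library, and they have no values in the text.

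The test was checked on simulated counts for the comparison of BPK25 with DMSO at day 0 over 17394 genes, 200 of them changed. It recovered 36%, 64%, 90% and 100% of the 50 genes changed 1.25, 1.5, 2 and 4-fold, with 0.685% false calls, and it made 0 calls in a comparison with no change. Where a group held 1 to 3 counts of a gene, the ratio of pooled rates is given with an exact 95% interval, and where it held 0 counts, a lower bound from a floor of 3 counts over the group, also with 1 library left out; both cover counting error only, since reads without molecular identifiers are not independent molecules. Alternatives were RLE size factors, DESeq2's Wald test, no filter, a stricter filter (1 CPM in 3 libraries), only the libraries compared, only the 9 libraries of a day, a replicate term, and leaving out each library in turn. A correlation counted as unchanged when it moved by less than 0.1. Leaving out 1 library leaves 2 in its group, and the fit then pools the spread over all groups. Tests of length, GC content and depth refitted the model with a trend removed or with all libraries thinned to the depth of the smallest library, 6621288 counts.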

Results

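Polyadenylated RNA was sequenced from mouse embryonic stem cells, pluripotent cells derived from the early embryo. Libraries were taken at days 0, 2, 4 and 6 under 3 treatments. DMSO is the usual solvent for compounds, and BPK25 is a compound known here only by its code name. IAA (auxin) triggers breakdown of a degron-tagged protein in cells that carry such a tag. The 12 groups had 3 libraries each, 36 in all, with 6621288 to 16497799 counts over genes per library. The series title concerns the NuRD chromatin remodelling complex, chromatin and genome architecture at CTCF sites. The labels used here do not state which protein is tagged, the dose, what the day is counted from, or whether DMSO and IAA libraries came from 1 clone. Nothing says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. In the text, ± after a log2 fold change is its size divided by the square root of the F value of the test. This approximates a standard error. It can lie below counting error for large changes at low counts, such as Gkn1 in IAA at day 6 with 11 counts. After a level in CPM (counts scaled to a common library total) ± is the SD over 3 libraries.

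Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.381 to 3.066 in 36 pairs. No pair was identical, but this cannot tell technical repeats from separate cultures, and each library was counted as 1 sample. By root mean square log2 distance, BPK25 lay 0.262, 0.274 and 0.233 from DMSO of the same day at days 0, 2 and 6, but 0.608 at day 4. The nearest group to BPK25 at day 4 was IAA at day 2, at 0.506. IAA lay 0.536, 0.715, 0.619 and 0.738 from DMSO of the same day at days 0, 2, 4 and 6. The mitochondrial share of counts at day 4 was 1.96% ± 0.103 in BPK25, 2.49% ± 0.0241 in IAA and 1.40% ± 0.0493 in DMSO (SD, n = 3). The labels name irradiated fibroblasts as typical feeder cells, which make collagens. The summed level of Col1a1, Col1a2 and Col3a1 in DMSO was 9.11 ± 1.24 CPM at day 0 and 61.1 ± 2.93 at day 6. At day 6 it was 89.6 ± 3.12 CPM in BPK25 and 201 ± 2.06 in IAA (SD, n = 3).

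**Figure D1:**
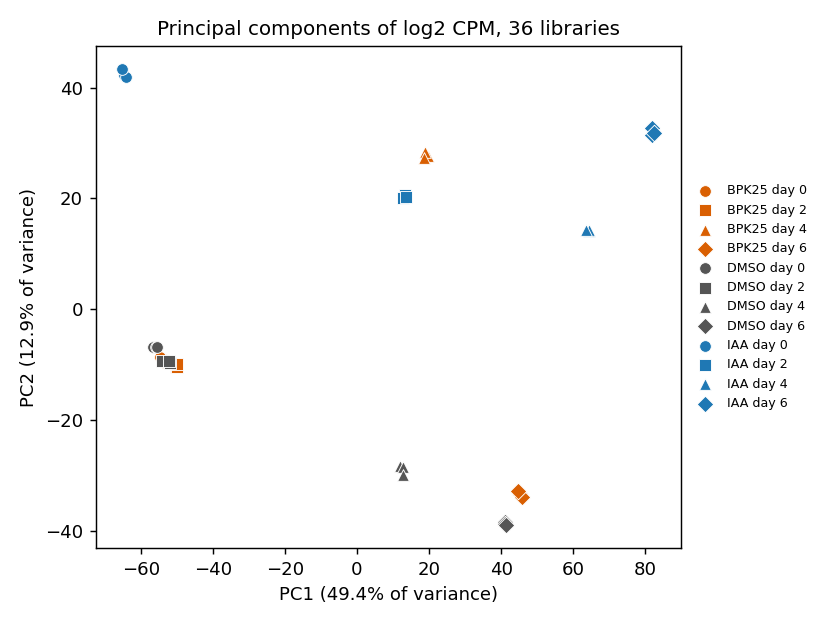
Principal components 1 (49.4% of variance) and 2 (12.9%) of log2 CPM for the 36 libraries, with color and marker giving treatment and day. The 3 libraries of each group lie close together, and BPK25 at day 4 sits away from DMSO at day 4.

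In DMSO alone, pluripotency genes fell over the 6 days and genes of several lineages rose. Tdgf1, which encodes the co-receptor of the growth factor Nodal, stood at 9.76 ± 0.985 CPM at day 6 against 165 ± 8.94 at day 0. Tdgf1 (-4.09 ± 0.07) and the Nodal antagonist genes Lefty1 (-5.54 ± 0.09) and Lefty2 (-5.39 ± 0.08) fell. Core pluripotency factors also fell, Pou5f1 (-2.0 ± 0.04), Sox2 (-2.08 ± 0.05) and Nanog (-2.53 ± 0.07). The fetal growth factor gene Igf2 (4.94 ± 0.13), the posterior patterning gene Hoxc8 (4.82 ± 0.25) and the somite gene Meox1 (5.38 ± 0.21) rose. Without DMSO day 0 replicate 3 the value of Meox1 was 6.53. The largest adjusted p among genes valued here was 1.57e-22 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Reads over Igf2 also fall on the overlapping model Gm49394, which held 48502 counts against 50387 for Igf2.

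Others among the lowest under the naming rule were the p53 family gene Trp73 (-4.84 ± 0.33) and the cAMP-activated exchange factor gene Rapgef3 (-4.03 ± 0.19). The muscle fusion gene Mymx (-3.98 ± 0.21) fell too, as did Smtnl1 (-3.92 ± 0.16), Tmem253 (-4.02 ± 0.30) and Ubap1l (-4.73 ± 0.26). Nphs1, which encodes the kidney protein nephrin, fell by 5.48 ± 0.38, and was lower by 126 times (exact interval 22.3 to 5.02e+03) without DMSO day 6 replicate 1. Pitpnm3 (4.70 ± 0.31) and the antisense transcript Hoxb5os (4.45 ± 0.26) rose. The strand setting of the counting is not given in the sources used here, so reads of Hoxb5os cannot be told from those of its partner. The bHLH inhibitor gene Id3 rose by 4.47 ± 0.25, or 5.26 without DMSO day 0 replicate 3. The cadherin gene Fat4 rose by 4.45 ± 0.37, or 37.1 times (exact interval 12.6 to 181) without DMSO day 0 replicate 1. The smooth muscle actin gene Acta2 was 154 times higher at day 6 (95% exact interval 27.3 to 6.09e+03). It was 101 times (exact interval 17.9 to 3.99e+03) without DMSO day 0 replicate 1. Without DMSO day 0 replicate 2, which held its only count at day 0, it was at least 33.1-fold higher (floor of 3 counts over the libraries left). The nicotinic receptor gene Chrna3 was 69.9 times higher (exact interval 19 to 581), or 45.8 times (exact interval 12.5 to 381) without DMSO day 0 replicate 1. Genes valued here each had an adjusted p of at most 8.62e-15 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

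Of 18 tested naive pluripotency genes, 0 rose, 18 fell and 0 did not pass, with 0 up and 18 down adjusted within the list (camera adjusted p = 4.8e-33). Examples were Esrrb (-2.51 ± 0.06) and Dppa5a (-2.0 ± 0.05). Among core pluripotency genes, 1 of 13 tested rose, 12 fell and 0 did not pass, with 1 up and 12 down adjusted within the list (camera adjusted p = 2.34e-28). 3 of the 14 tested formative and primed genes rose, 9 fell and 2 did not pass, with 3 up and 9 down adjusted within the list (camera adjusted p = 0.00595). Otx2 (-2.21 ± 0.15) fell and Cdh2 (1.76 ± 0.11) rose. For endoderm genes, 15 of 19 tested rose, 3 fell and 1 did not pass, with 15 up and 3 down adjusted within the list (camera adjusted p = 1.9e-15). They included basement membrane genes, Lama1 (1.71 ± 0.03) and Lamb1 (1.54 ± 0.04). Of 17 tested neural genes, 12 rose, 2 fell and 3 did not pass, with 12 up and 3 down adjusted within the list (camera adjusted p = 0.0295). Pax6 (1.64 ± 0.09) and Nes (1.30 ± 0.09) rose while Stmn2 (-2.58 ± 0.07) fell. Among trophectoderm genes, 10 of 14 tested rose, 2 fell and 2 did not pass, with 10 up and 2 down adjusted within the list (camera adjusted p = 5.44e-05). Keratin genes rose, Krt18 (2.26 ± 0.08) and Krt8 (1.62 ± 0.07). 3 of the 8 tested primitive streak and mesoderm genes rose, 3 fell and 2 did not pass, with 3 up and 3 down adjusted within the list (camera adjusted p = 0.81). For cardiac and blood vessel genes, 6 of 15 tested rose, 2 fell and 7 did not pass, with 5 up and 2 down adjusted within the list (camera adjusted p = 0.621). Of 19 tested 2-cell-like genes, 19 rose, 0 fell and 0 did not pass, with 19 up and 0 down adjusted within the list (camera adjusted p = 2.17e-16). These genes mark a rare state of such cultures, and the Zscan4 and Usp17l members are near-identical copies, so counts of single members such as Zscan4d are uncertain. Among imprinted genes, 19 of 26 tested rose, 2 fell and 5 did not pass, with 19 up and 2 down adjusted within the list (camera adjusted p = 1.83e-16). 19 of the 34 tested Hox genes rose, 4 fell and 11 did not pass, with 19 up and 4 down adjusted within the list (camera adjusted p = 8.46e-05). Peg3 (2.31 ± 0.04) and Hoxb8 (1.74 ± 0.07) were among them. By edgeR's quasi-likelihood test, Benjamini-Hochberg, the largest adjusted p of the genes valued was 3.6e-17.

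The integrated stress response includes an ATF4-driven program of amino acid supply. For integrated stress response genes, 2 of 20 tested rose, 16 fell and 2 did not pass, with 2 up and 16 down adjusted within the list (camera adjusted p = 2.2e-15). Cth (-2.57 ± 0.10) and Pck2 (-1.83 ± 0.06) fell. Of 23 tested p53 targets, 3 rose, 15 fell and 5 did not pass, with 3 up and 15 down adjusted within the list (camera adjusted p = 5.44e-05). Among cholesterol synthesis genes, 2 of 25 tested rose, 19 fell and 4 did not pass, with 2 up and 20 down adjusted within the list (camera adjusted p = 1.58e-05). 1 of the 20 tested mitosis genes rose, 16 fell and 3 did not pass, with 1 up and 16 down adjusted within the list (camera adjusted p = 6.63e-06). For heat shock genes, 5 of 18 tested rose, 9 fell and 4 did not pass, with 5 up and 9 down adjusted within the list (camera adjusted p = 0.0244, adjusted p = 0.16 with an estimated correlation). Of 13 tested mitochondrially encoded genes, 10 rose, 0 fell and 3 did not pass, with 10 up and 0 down adjusted within the list (camera adjusted p = 0.00565, adjusted p = 0.169 with an estimated correlation). Among fibroblast feeder markers, 17 of 20 tested rose, 1 fell and 2 did not pass, with 17 up and 1 down adjusted within the list (camera adjusted p = 9.03e-07). The microfibril gene Fbn1 (1.77 ± 0.06) rose. 23 of the 36 tested clustered protocadherin genes rose, 0 fell and 13 did not pass, with 23 up and 0 down adjusted within the list (camera adjusted p = 0.0402, adjusted p = 0.601 with an estimated correlation). The 22 gamma protocadherins share exons, their counts had a median pairwise correlation of 0.995, and they act as close to 1 measurement. No gene given a value here had an adjusted p above 6.11e-28 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

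In all, 5781 genes were higher and 5132 lower at day 6 than at day 0 in DMSO, of 17394 tested, with 1843 and 1385 of them at least 2-fold. At day 4 the numbers were 4514 and 4237. At day 2, 276 were higher and 670 lower (379 lower in a fit of only the libraries compared), with 20 and 13 at least 2-fold. For core pluripotency genes, 0 of 13 tested rose, 6 fell and 7 did not pass, with 0 up and 9 down adjusted within the list (camera adjusted p = 2.89e-12). L1td1 (-0.52 ± 0.05) fell. Of 15 tested CTCF and cohesin genes, 0 rose, 2 fell and 13 did not pass, with 0 up and 5 down adjusted within the list (camera adjusted p = 0.0203, adjusted p = 0.271 with an estimated correlation). No other comparison called that list by camera. With edgeR's quasi-likelihood test, Benjamini-Hochberg, every adjusted p of the genes valued was at most 9.04e-10. The day 2 numbers depended on single libraries. Without DMSO day 0 replicate 1, DMSO day 0 replicate 3 or DMSO day 2 replicate 3, 147, 164 and 124 genes were higher and 321, 410 and 288 lower.

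**Figure D2:**
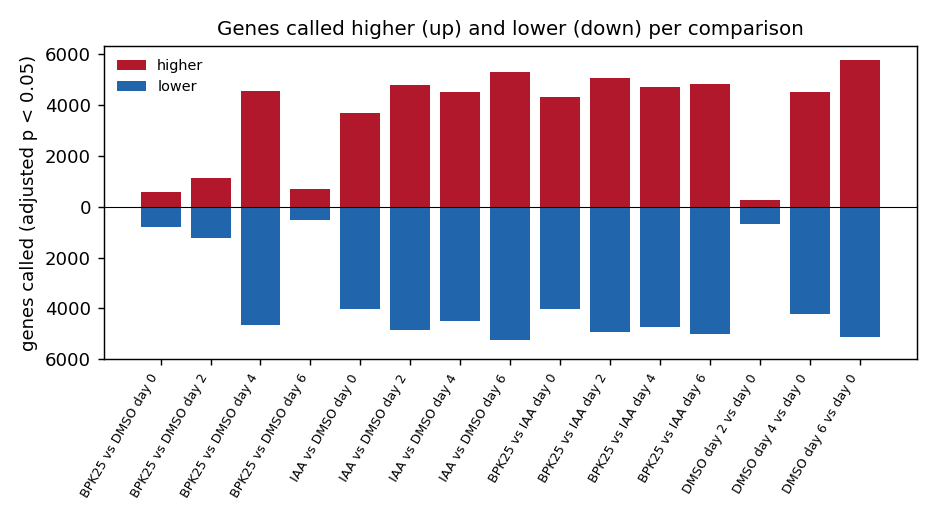
Number of genes called higher (red, upward) and lower (blue, downward) at adjusted p under 0.05 in each comparison, 3 libraries against 3, of 17394 tested. BPK25 against DMSO gave 577 and 797 genes at day 0 but 4562 and 4654 at day 4.

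At day 0 BPK25 differed little from DMSO, and the clearest group was the integrated stress response. Among integrated stress response genes, 10 of 20 tested rose, 0 fell and 10 did not pass, with 15 up and 0 down adjusted within the list (camera adjusted p = 2.28e-15). They included the mitochondrial folate enzyme gene Mthfd2 (0.42 ± 0.05), the stress factor gene Ddit3 (0.49 ± 0.07), Pck2 (0.26 ± 0.05) and Phgdh (0.37 ± 0.05), which starts serine synthesis. Ddit3 stood at 90.0 ± 6.30 CPM against 63.5 ± 5.99 in DMSO. Mtln (0.78 ± 0.12), which encodes a small mitochondrial protein, and the histone gene Hist1h2af (0.69 ± 0.08) rose. The cilia-related gene Lztfl1 (-0.64 ± 0.13) fell. Replication-dependent histone messages mostly lack poly(A) tails, so histone counts here cover an uncertain part of them. For the genes given values, adjusted p reached at most 0.000955 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

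The other 5 lists called at day 0 each lost their call with an estimated correlation. 0 of the 13 tested mitochondrially encoded genes rose, 4 fell and 9 did not pass, with 0 up and 6 down adjusted within the list (camera adjusted p = 0.007, adjusted p = 0.261 with an estimated correlation). For core pluripotency genes, 0 of 13 tested rose, 2 fell and 11 did not pass, with 0 up and 4 down adjusted within the list (camera adjusted p = 0.0182, adjusted p = 0.0546 with an estimated correlation). Examples were mt-Nd5 (-0.24 ± 0.04), mt-Co1 (-0.25 ± 0.04), Dppa2 (-0.25 ± 0.05) and L1td1 (-0.24 ± 0.05). Of 36 tested clustered protocadherin genes, 21 rose, 0 fell and 15 did not pass, with 22 up and 0 down adjusted within the list (camera adjusted p = 4.89e-09, adjusted p = 0.261 with an estimated correlation). Among 2-cell-like genes, 1 of 19 tested rose, 0 fell and 18 did not pass, with 1 up and 0 down adjusted within the list (camera adjusted p = 0.0196, adjusted p = 0.081 with an estimated correlation). 1 of the 20 tested fibroblast feeder markers rose, 0 fell and 19 did not pass, with 1 up and 0 down adjusted within the list (camera adjusted p = 0.0318, adjusted p = 0.0694 with an estimated correlation). The largest adjusted p among genes valued here was 0.00114 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

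In all, 577 genes were higher and 797 lower in BPK25 at day 0, with 23 and 6 at least 2-fold. With no filter on low counts 606 were higher and 402 lower, so which direction has more calls depends on the filter. Several genes that met the naming rule lost their call with 1 library left out. Rhox9 (0.89 ± 0.21) lost its call without DMSO day 0 replicate 2 (0.70). The cilia factor gene Rfx3 (-0.60 ± 0.14) lost it without DMSO day 0 replicate 3 (-0.41). The glycolytic gene Aldoc (-0.59 ± 0.16) lost it without BPK25 day 0 replicate 2 (-0.56) or DMSO day 0 replicate 2 (-0.58). For mt-Nd6 (-0.64 ± 0.18) this held without BPK25 day 0 replicate 3 (-0.56), DMSO day 0 replicate 2 (-0.61) or DMSO day 0 replicate 3 (-0.61). Genes higher were 375 and 359 without DMSO day 0 replicate 1 or 2. Genes lower were 439 without BPK25 day 0 replicate 1, and 500, 485 and 517 without DMSO day 0 replicate 1, 2 or 3.

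At day 2 the stress response genes were again higher in BPK25, including Phgdh (0.51 ± 0.05), Ddit3 (0.48 ± 0.06), Pck2 (0.31 ± 0.05) and Aldh1l2 (0.64 ± 0.10), another mitochondrial folate enzyme gene. For integrated stress response genes, 14 of 20 tested rose, 0 fell and 6 did not pass, with 15 up and 0 down adjusted within the list (camera adjusted p = 7.4e-16). The lipolysis inhibitor gene G0s2 (1.01 ± 0.18), Plet1 (0.85 ± 0.17), Bloc1s4 (0.89 ± 0.15) and the histone gene Hist1h2ao (0.88 ± 0.11) were among the highest under the naming rule. Among the lowest were Cox17 (-0.77 ± 0.07), which encodes the copper chaperone of cytochrome oxidase, and the ribosomal protein gene Rps28 (-0.79 ± 0.12). Chchd7 (-0.87 ± 0.12), Zfp692 (-0.86 ± 0.09) and the TFIIH subunit gene Gtf2h2 (-0.76 ± 0.07) fell as well. Of 19 tested hypoxia and glycolysis genes, 1 rose, 5 fell and 13 did not pass, with 1 up and 7 down adjusted within the list (camera adjusted p = 0.0365, adjusted p = 0.171 with an estimated correlation). The mitophagy receptor gene Bnip3 (-0.70 ± 0.09) and P4ha1 (-0.27 ± 0.04) fell and Vegfa (0.30 ± 0.06) rose. Among mitochondrially encoded genes, 0 of 13 tested rose, 3 fell and 10 did not pass, with 0 up and 3 down adjusted within the list (camera adjusted p = 0.00156, adjusted p = 0.191 with an estimated correlation). 19 of the 36 tested clustered protocadherin genes rose, 0 fell and 17 did not pass, with 21 up and 0 down adjusted within the list (camera adjusted p = 6.54e-06, adjusted p = 0.327 with an estimated correlation). Genes valued here each had an adjusted p of at most 0.000377 (edgeR's quasi-likelihood test, Benjamini-Hochberg). In all, 1114 genes were higher and 1238 lower (1057 and 881 with no filter), with 46 and 21 at least 2-fold.

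At day 4 BPK25 libraries carried strong increases in genes of xenobiotic and oxidative stress. Cyp1a1, a monooxygenase gene induced through the aryl hydrocarbon receptor, stood at 66.6 ± 2.47 CPM against 1.30 ± 0.257 in DMSO. Cyp1a1 (5.63 ± 0.14), the fetal liver protein gene Afp (4.76 ± 0.19) and Ccn1 (4.48 ± 0.07), a matrix protein gene induced by YAP, rose. The gastrokine gene Gkn1 was 198 times lower than in DMSO (95% exact interval 67.2 to 961). Gkn2 was at 0.127 ± 0.124 CPM against 21.4 ± 1.57 in DMSO. The mucin-like gene Mucl3 (-4.39 ± 0.19), Fam167a (-3.30 ± 0.21) and the antisense transcript Trpc5os (-4.64 ± 0.27) fell. The strand limit on Hoxb5os holds for Trpc5os as well. By edgeR's quasi-likelihood test, Benjamini-Hochberg, the largest adjusted p of the genes valued was 1.25e-18.

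For aryl hydrocarbon receptor targets, 5 of 7 tested rose, 1 fell and 1 did not pass, with 5 up and 1 down adjusted within the list (camera adjusted p = 2.03e-11). Tiparp (1.53 ± 0.05) and Cyp1b1 (2.26 ± 0.12) rose. NRF2 is the main regulator of antioxidant genes. Of 24 tested NRF2 targets, 20 rose, 2 fell and 2 did not pass, with 20 up and 2 down adjusted within the list (camera adjusted p = 9.26e-16). The sulfiredoxin gene Srxn1 (1.74 ± 0.06), the thioredoxin reductase gene Txnrd1 (1.15 ± 0.04) and Gstm1 (1.89 ± 0.09) rose. Among integrated stress response genes, 14 of 20 tested rose, 1 fell and 5 did not pass, with 14 up and 1 down adjusted within the list (camera adjusted p = 1.02e-05). Atf3 (2.02 ± 0.12) and Ddit3 (1.26 ± 0.06) rose while Pck2 (-0.81 ± 0.07) fell. 14 of the 23 tested p53 targets rose, 4 fell and 5 did not pass, with 15 up and 4 down adjusted within the list (camera adjusted p = 8.68e-05). They included Mdm2 (0.93 ± 0.05) and the cell cycle inhibitor gene Cdkn1a (1.21 ± 0.09). For hypoxia and glycolysis genes, 15 of 19 tested rose, 3 fell and 1 did not pass, with 15 up and 3 down adjusted within the list (camera adjusted p = 1.43e-10). Aldoa (1.18 ± 0.04) and Ldha (1.05 ± 0.04) rose. Of 18 tested heat shock genes, 3 rose, 10 fell and 5 did not pass, with 3 up and 10 down adjusted within the list (camera adjusted p = 0.0163, adjusted p = 0.111 with an estimated correlation). Hsp90aa1 (0.72 ± 0.05) rose. Among mitochondrially encoded genes, 11 of 13 tested rose, 0 fell and 2 did not pass, with 11 up and 0 down adjusted within the list (camera adjusted p = 0.000936, adjusted p = 0.0979 with an estimated correlation). 0 of the 36 tested clustered protocadherin genes rose, 22 fell and 14 did not pass, with 0 up and 22 down adjusted within the list (camera adjusted p = 0.000255, adjusted p = 0.324 with an estimated correlation). No gene given a value here had an adjusted p above 6.49e-15 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

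For endoderm genes, 6 of 19 tested rose, 11 fell and 2 did not pass, with 6 up and 11 down adjusted within the list (camera adjusted p = 0.00219). Lama1 (-1.66 ± 0.03) fell while Apoe (1.5 ± 0.04) and Apoa1 (3.15 ± 0.16) rose. The list's median (-0.59) and test were negative, its mean positive (0.18). Of 14 tested trophectoderm genes, 7 rose, 2 fell and 5 did not pass, with 7 up and 2 down adjusted within the list (camera adjusted p = 0.00313). Among formative and primed genes, 1 of 14 tested rose, 6 fell and 7 did not pass, with 1 up and 6 down adjusted within the list (camera adjusted p = 0.0214). Krt18 (1.86 ± 0.07) and Krt19 (1.36 ± 0.13) rose, and the DNA methyltransferase gene Dnmt3b (-1.08 ± 0.05) and Zic2 (-1.18 ± 0.14) fell. 2 of the 19 tested 2-cell-like genes rose, 16 fell and 1 did not pass, with 2 up and 16 down adjusted within the list (camera adjusted p = 0.000111). For mitosis genes, 3 of 20 tested rose, 13 fell and 4 did not pass, with 3 up and 13 down adjusted within the list (camera adjusted p = 0.0318, adjusted p = 0.0979 with an estimated correlation). Mki67 (0.55 ± 0.04) rose and Bub1b (-0.51 ± 0.05) fell. Of 25 tested cholesterol synthesis genes, 1 rose, 12 fell and 12 did not pass, with 1 up and 12 down adjusted within the list (camera adjusted p = 0.0253, adjusted p = 0.119 with an estimated correlation). Among interferon-stimulated genes, 3 of 13 tested rose, 5 fell and 5 did not pass, with 3 up and 5 down adjusted within the list (camera adjusted p = 0.959). No comparison called that list by camera. 8 of the 20 tested fibroblast feeder markers rose, 5 fell and 7 did not pass, with 8 up and 5 down adjusted within the list (camera adjusted p = 0.0664). The collagen sum was 9.98 ± 1.04 CPM in BPK25 and 18.4 ± 1.15 in DMSO (SD, n = 3). With edgeR's quasi-likelihood test, Benjamini-Hochberg, every adjusted p of the genes valued was at most 6.41e-10.

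In all, 4562 genes were higher and 4654 lower at day 4 (4474 and 4462 with no filter), with 1081 and 686 at least 2-fold. The YAP target gene Ankrd1 rose by 4.64 ± 0.34, or 43.2 times (exact interval 14.6 to 211) without DMSO day 4 replicate 2. The fitted log2 change of Gkn2 was -7.21, and -6.62 without BPK25 day 4 replicate 3. Without BPK25 day 4 replicate 1 it was lower by 389 times (exact interval 69.6 to 1.54e+04), and without replicate 3 Gkn1 was lower by 384 times (exact interval 68.6 to 1.52e+04). The collectin gene Colec11 was 85.2 times higher in BPK25 (95% exact interval 28.9 to 416). A single library carried most of its counts, with a level of 8.33 ± 10.2 CPM. Without BPK25 day 4 replicate 1 it was higher by 20.2 times (exact interval 6.44 to 102) and without replicate 3 by 130 times (exact interval 43.9 to 632).

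By day 6 BPK25 libraries again lay close to DMSO, with stress response and imprinted genes higher. For integrated stress response genes, 10 of 20 tested rose, 0 fell and 10 did not pass, with 12 up and 1 down adjusted within the list (camera adjusted p = 6.15e-09). Trib3 (0.85 ± 0.16), a pseudokinase gene of that program, Nupr1 (0.52 ± 0.09) and Phgdh (0.36 ± 0.05) rose. Of 26 tested imprinted genes, 9 rose, 0 fell and 17 did not pass, with 11 up and 1 down adjusted within the list (camera adjusted p = 2.63e-08). Igf2 (0.62 ± 0.06), Plagl1 (0.39 ± 0.06) and Peg3 (0.26 ± 0.04) rose. The oocyte growth factor gene Gdf9 (0.91 ± 0.22), the matrix gene Ccdc80 (0.87 ± 0.17) and the immunoglobulin receptor gene Pigr (0.86 ± 0.19) were among the highest under the naming rule. Arxes2 (-0.57 ± 0.12) fell, as did Trmt12 (-0.56 ± 0.13) and Lcmt2 (-0.56 ± 0.12), which encode tRNA-modifying enzymes. For the genes given values, adjusted p reached at most 0.00576 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

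Among fibroblast feeder markers, 6 of 20 tested rose, 0 fell and 14 did not pass, with 7 up and 1 down adjusted within the list (camera adjusted p = 5.78e-07). The collagen genes Col1a1 (0.72 ± 0.08) and Col3a1 (0.62 ± 0.09) and the smooth muscle gene Tagln (0.51 ± 0.08) rose. 5 of the 14 tested trophectoderm genes rose, 0 fell and 9 did not pass, with 6 up and 1 down adjusted within the list (camera adjusted p = 0.00651). For 2-cell-like genes, 0 of 19 tested rose, 2 fell and 17 did not pass, with 0 up and 2 down adjusted within the list (camera adjusted p = 0.000114). Of 36 tested clustered protocadherin genes, 0 rose, 0 fell and 36 did not pass, with 0 up and 0 down adjusted within the list (camera adjusted p = 9.34e-05, adjusted p = 0.392 with an estimated correlation). Among cardiac and blood vessel genes, 2 of 15 tested rose, 0 fell and 13 did not pass, with 5 up and 0 down adjusted within the list (camera adjusted p = 0.00287). Of 15 NuRD genes, 2 rose, 0 fell and 13 did not pass, with 3 up and 0 down adjusted within the list (camera adjusted p = 0.00328, 0.087 with an estimated correlation). Camera called it nowhere else, but 3, 5 and 6 rose and 3, 3 and 6 fell in BPK25 at days 0, 2 and 4. Mta2 (0.36 ± 0.05) rose. For cholesterol synthesis genes, 0 of 25 tested rose, 4 fell and 21 did not pass, with 0 up and 5 down adjusted within the list (camera adjusted p = 5.07e-05). Of 23 tested p53 targets, 1 rose, 4 fell and 18 did not pass, with 1 up and 4 down adjusted within the list (camera adjusted p = 0.00883). Among NRF2 targets, 0 of 24 tested rose, 3 fell and 21 did not pass, with 0 up and 3 down adjusted within the list (camera adjusted p = 0.0173, adjusted p = 0.097 with an estimated correlation). Acat2 (-0.27 ± 0.06), Bax (-0.33 ± 0.06) and Srxn1 (-0.47 ± 0.07) fell. 6 of the 13 tested mitochondrially encoded genes rose, 0 fell and 7 did not pass, with 8 up and 0 down adjusted within the list (camera adjusted p = 2.86e-05). The largest adjusted p among genes valued here was 0.00157 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

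The day 6 comparison gave 698 genes higher and 535 lower, with 14 and 5 at least 2-fold. DESeq2 gave 330 lower, and both numbers moved with single libraries. Without BPK25 day 6 replicate 1 or 3 or DMSO day 6 replicate 1 or 3, 446, 452, 320 and 455 were higher and 300, 313, 224 and 335 lower. The muscle gene Lmod1 (0.82 ± 0.20) lost its call without BPK25 day 6 replicate 3 (0.69) or DMSO day 6 replicate 1 (0.66). Tpbgl (-0.60 ± 0.17) lost it without BPK25 day 6 replicate 1 (-0.47) or 3 (-0.61). It also lost it without DMSO day 6 replicate 1 (-0.64), 2 (-0.58) or 3 (-0.57). Zfp296 (-0.62 ± 0.20) lost it without any 1 of the 6 libraries compared, at -0.54 to -0.68, and with RLE, DESeq2 or a replicate term.

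Under IAA, day 0 already showed broad differences from DMSO, with naive pluripotency and glycolysis genes higher. For naive pluripotency genes, 11 of 18 tested rose, 3 fell and 4 did not pass, with 12 up and 3 down adjusted within the list (camera adjusted p = 8.23e-10). Klf4 (1.14 ± 0.05), Tfcp2l1 (1.01 ± 0.05) and the growth factor gene Fgf4 (1.74 ± 0.09) rose. Tdgf1 stood at 355 ± 6.46 CPM against 165 ± 8.94 in DMSO. Among the highest under the naming rule were the potassium channel gene Kcnh3 (3.92 ± 0.31), Aire (3.58 ± 0.26), which regulates thymic self-antigens, and the surface protein gene Thy1 (3.31 ± 0.38). Among the lowest were Zfp629 (-2.42 ± 0.25), the matrix protein gene Mgp (-2.23 ± 0.29) and the gastrokine genes Gkn1 (-2.14 ± 0.16) and Gkn2 (-2.07 ± 0.16). Cyp26a1, which encodes a retinoic acid-degrading enzyme, fell by 2.04 ± 0.05. Genes valued here each had an adjusted p of at most 9.56e-09 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

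Of 19 tested hypoxia and glycolysis genes, 15 rose, 2 fell and 2 did not pass, with 15 up and 2 down adjusted within the list (camera adjusted p = 1.76e-31). Ldha (1.35 ± 0.04) and Pfkl (1.34 ± 0.06) rose. Among core pluripotency genes, 7 of 13 tested rose, 3 fell and 3 did not pass, with 7 up and 3 down adjusted within the list (camera adjusted p = 0.0313). Sox2 (0.55 ± 0.05) rose and Dppa2 (-0.58 ± 0.05) fell. 14 of the 23 tested p53 targets rose, 3 fell and 6 did not pass, with 16 up and 4 down adjusted within the list (camera adjusted p = 0.000646). Pmaip1 (0.84 ± 0.06) rose. For germline genes, 0 of 20 tested rose, 16 fell and 4 did not pass, with 0 up and 16 down adjusted within the list (camera adjusted p = 1.46e-09). The RNA-binding protein gene Dazl (-1.37 ± 0.05) and Mael (-1.03 ± 0.10) fell. Of 19 tested 2-cell-like genes, 0 rose, 11 fell and 8 did not pass, with 0 up and 11 down adjusted within the list (camera adjusted p = 0.00325). Among trophectoderm genes, 6 of 14 tested rose, 0 fell and 8 did not pass, with 6 up and 0 down adjusted within the list (camera adjusted p = 0.0231). 1 of the 19 tested endoderm genes rose, 15 fell and 3 did not pass, with 1 up and 15 down adjusted within the list (camera adjusted p = 7.28e-10). For Hox genes, 4 of 34 tested rose, 18 fell and 12 did not pass, with 4 up and 18 down adjusted within the list (camera adjusted p = 0.000163). Dab2 (-0.71 ± 0.04) and Hoxb8 (-1.49 ± 0.11) fell. Of 20 tested integrated stress response genes, 3 rose, 16 fell and 1 did not pass, with 3 up and 16 down adjusted within the list (camera adjusted p = 0.000163). Among imprinted genes, 3 of 26 tested rose, 13 fell and 10 did not pass, with 3 up and 13 down adjusted within the list (camera adjusted p = 0.0326). H19 (-1.15 ± 0.08) fell although Peg10 (1.15 ± 0.04) rose. 11 of the 13 tested mitochondrially encoded genes rose, 1 fell and 1 did not pass, with 11 up and 1 down adjusted within the list (camera adjusted p = 3.57e-06). By edgeR's quasi-likelihood test, Benjamini-Hochberg, the largest adjusted p of the genes valued was 1.42e-12. In all, 3709 genes were higher and 4027 lower, with 786 and 477 at least 2-fold. The ganglioside synthase gene St8sia1 rose by 3.73 ± 0.29, or 4.42 without DMSO day 0 replicate 3.

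At day 2 IAA libraries had less pluripotency expression than DMSO and more Hox and imprinted gene expression. Tdgf1 was at 9.38 ± 0.571 CPM against 138 ± 17.4 in DMSO, and Lefty2 fell by 4.47 ± 0.08. The retinoic acid-binding protein gene Crabp2 stood at 408 ± 13.2 CPM against 21.7 ± 1.37 in DMSO. The retinaldehyde dehydrogenase gene Aldh1a1 (4.25 ± 0.29), Meox1 (4.92 ± 0.20) and Igf2 (4.35 ± 0.15) rose. Phf11b (-4.20 ± 0.30) fell. Gkn1 was 305 times lower than in DMSO (95% exact interval 83.9 to 2.52e+03). Gkn2 was 215 times lower (exact interval 73.3 to 1.05e+03), or 418 times (exact interval 74.7 to 1.65e+04) without IAA day 2 replicate 2. Mgp had a fitted log2 change of -5.13, and was lower by 59.8 times (exact interval 16.3 to 498) without IAA day 2 replicate 3. Hoxc8 rose by 5.62 ± 0.26, or 94 times (exact interval 32 to 458) without DMSO day 2 replicate 2. No gene given a value here had an adjusted p above 5.19e-17 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

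For naive pluripotency genes, 0 of 18 tested rose, 17 fell and 1 did not pass, with 0 up and 17 down adjusted within the list (camera adjusted p = 1.54e-13). Of 13 tested core pluripotency genes, 1 rose, 12 fell and 0 did not pass, with 1 up and 12 down adjusted within the list (camera adjusted p = 6.82e-11). Examples were Nr0b1 (-2.78 ± 0.11), Nanog (-1.19 ± 0.06), Sox2 (-0.98 ± 0.05) and Pou5f1 (-0.67 ± 0.04). Among 2-cell-like genes, 16 of 19 tested rose, 0 fell and 3 did not pass, with 16 up and 0 down adjusted within the list (camera adjusted p = 4.08e-20). 23 of the 34 tested Hox genes rose, 5 fell and 6 did not pass, with 25 up and 5 down adjusted within the list (camera adjusted p = 4.29e-08). For imprinted genes, 15 of 26 tested rose, 4 fell and 7 did not pass, with 15 up and 5 down adjusted within the list (camera adjusted p = 5.91e-08). Hoxb8 (1.80 ± 0.07), Hoxc9 (3.21 ± 0.20), Peg10 (2.72 ± 0.04) and Mest (2.18 ± 0.05) rose. Of 19 tested endoderm genes, 12 rose, 4 fell and 3 did not pass, with 12 up and 4 down adjusted within the list (camera adjusted p = 0.0105). Among trophectoderm genes, 8 of 14 tested rose, 1 fell and 5 did not pass, with 8 up and 1 down adjusted within the list (camera adjusted p = 0.0105). Krt18 (2.02 ± 0.09) rose while Lama1 (-0.55 ± 0.03) fell. 2 of the 20 tested integrated stress response genes rose, 14 fell and 4 did not pass, with 3 up and 14 down adjusted within the list (camera adjusted p = 8.21e-08). Nupr1 (-2.06 ± 0.10) and Cth (-1.86 ± 0.09) fell. For hypoxia and glycolysis genes, 12 of 19 tested rose, 5 fell and 2 did not pass, with 12 up and 6 down adjusted within the list (camera adjusted p = 0.0416, adjusted p = 0.0692 with an estimated correlation). Of 36 tested clustered protocadherin genes, 23 rose, 0 fell and 13 did not pass, with 23 up and 0 down adjusted within the list (camera adjusted p = 0.0105, adjusted p = 0.48 with an estimated correlation). Among p53 targets, 1 of 23 tested rose, 11 fell and 11 did not pass, with 1 up and 11 down adjusted within the list (camera adjusted p = 0.0105). With edgeR's quasi-likelihood test, Benjamini-Hochberg, every adjusted p of the genes valued was at most 2.61e-19. In all, 4777 genes were higher and 4861 lower, with 1135 and 1222 at least 2-fold.

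At day 4 imprinted, trophectoderm and endoderm genes were higher in IAA than in DMSO. Igf2 was at 410.2 ± 1.78 CPM against 9.13 ± 1.34 in DMSO, and the imprinted zinc finger gene Plagl1 (3.24 ± 0.07) and the glutathione peroxidase gene Gpx2 (4.36 ± 0.17), Nepn (4.60 ± 0.23) and Clca1 (4.29 ± 0.34) rose. Gkn1 had 0 of 33386903 counts in 3 libraries, at least 219-fold lower than in DMSO (floor of 3 counts, 0.0899 CPM), or 137-fold without IAA day 4 replicate 3. Gkn2 (-5.76 ± 0.22), Mucl3 (-4.02 ± 0.18), Trpc5os (-3.76 ± 0.23) and the unconventional myosin gene Myo7a (-3.51 ± 0.07) fell. Acta2 rose by 4.95 ± 0.21, or 5.67 without DMSO day 4 replicate 1. For the genes given values, adjusted p reached at most 2.01e-15 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

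16 of the 26 tested imprinted genes rose, 6 fell and 4 did not pass, with 16 up and 6 down adjusted within the list (camera adjusted p = 1.26e-30). For trophectoderm genes, 10 of 14 tested rose, 0 fell and 4 did not pass, with 11 up and 0 down adjusted within the list (camera adjusted p = 3.62e-16). Of 19 tested endoderm genes, 13 rose, 2 fell and 4 did not pass, with 13 up and 2 down adjusted within the list (camera adjusted p = 2.75e-14). Krt19 (3.10 ± 0.10), Gata3 (3.05 ± 0.16), Col4a1 (1.23 ± 0.04) and Apoa1 (3.31 ± 0.16) rose. Among primitive streak and mesoderm genes, 3 of 8 tested rose, 0 fell and 5 did not pass, with 3 up and 0 down adjusted within the list (camera adjusted p = 0.0454, adjusted p = 0.0594 with an estimated correlation). The vascular receptor gene Kdr (2.0 ± 0.12) and Foxf1 (3.06 ± 0.22) rose. 16 of the 19 tested hypoxia and glycolysis genes rose, 2 fell and 1 did not pass, with 16 up and 2 down adjusted within the list (camera adjusted p = 3.66e-18). For mitochondrially encoded genes, 12 of 13 tested rose, 0 fell and 1 did not pass, with 12 up and 0 down adjusted within the list (camera adjusted p = 5.23e-08). Of 18 tested naive pluripotency genes, 3 rose, 11 fell and 4 did not pass, with 3 up and 12 down adjusted within the list (camera adjusted p = 0.000401). Among 2-cell-like genes, 0 of 19 tested rose, 13 fell and 6 did not pass, with 0 up and 13 down adjusted within the list (camera adjusted p = 0.00513). 2 of the 20 tested integrated stress response genes rose, 13 fell and 5 did not pass, with 3 up and 13 down adjusted within the list (camera adjusted p = 3.02e-05). For mitosis genes, 1 of 20 tested rose, 15 fell and 4 did not pass, with 1 up and 15 down adjusted within the list (camera adjusted p = 6.44e-05). Nupr1 (-2.77 ± 0.17) and Ccnb1 (-0.63 ± 0.04) fell. Of 20 tested fibroblast feeder markers, 10 rose, 4 fell and 6 did not pass, with 10 up and 5 down adjusted within the list (camera adjusted p = 0.00341). The collagen sum was 38.7 CPM in IAA and 18.4 in DMSO. The largest adjusted p among genes valued here was 4.9e-17 (edgeR's quasi-likelihood test, Benjamini-Hochberg). In all, 4511 genes were higher and 4510 lower, with 1097 and 677 at least 2-fold.

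At day 6 IAA libraries lay farthest from DMSO of the same day. Igf2 was at 1077 ± 11.4 CPM against 66.5 ± 2.32 in DMSO, and the water channel gene Aqp1 (4.45 ± 0.17), the tight junction gene Cldn11 (4.15 ± 0.27) and Dmkn (4.14 ± 0.10) rose. The long noncoding RNA gene Fendrr, divergent from Foxf1 and under the same strand limit, rose by 3.96 ± 0.34. Gkn1 (-7.93 ± 0.16), Gkn2 (-6.97 ± 0.14) and Mucl3 (-6.92 ± 0.12) fell. Cyp1a1 was 55.5 times lower than in DMSO (95% exact interval 18.8 to 271). Without IAA day 6 replicate 3 it was lower by 115 times (exact interval 20.5 to 4.57e+03). Genes valued here each had an adjusted p of at most 1.06e-12 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

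Among imprinted genes, 17 of 26 tested rose, 6 fell and 3 did not pass, with 17 up and 6 down adjusted within the list (camera adjusted p = 2.65e-26). Meg3 (2.03 ± 0.04) and Dlk1 (2.76 ± 0.06) rose. 11 of the 14 tested trophectoderm genes rose, 2 fell and 1 did not pass, with 11 up and 2 down adjusted within the list (camera adjusted p = 8.9e-08). For hypoxia and glycolysis genes, 16 of 19 tested rose, 3 fell and 0 did not pass, with 16 up and 3 down adjusted within the list (camera adjusted p = 4.78e-12). Of 24 tested NRF2 targets, 12 rose, 5 fell and 7 did not pass, with 12 up and 5 down adjusted within the list (camera adjusted p = 0.00181). Krt18 (2.08 ± 0.05), Slc2a3 (0.95 ± 0.04) and Gstm1 (2.84 ± 0.07) rose. Among 2-cell-like genes, 0 of 19 tested rose, 18 fell and 1 did not pass, with 0 up and 18 down adjusted within the list (camera adjusted p = 2.51e-13). 2 of the 18 tested naive pluripotency genes rose, 10 fell and 6 did not pass, with 2 up and 11 down adjusted within the list (camera adjusted p = 0.021). For integrated stress response genes, 3 of 20 tested rose, 13 fell and 4 did not pass, with 3 up and 14 down adjusted within the list (camera adjusted p = 0.00101). Of 25 tested cholesterol synthesis genes, 1 rose, 20 fell and 4 did not pass, with 1 up and 20 down adjusted within the list (camera adjusted p = 0.00152). Asns (-0.89 ± 0.06) fell. Among fibroblast feeder markers, 11 of 20 tested rose, 6 fell and 3 did not pass, with 11 up and 6 down adjusted within the list (camera adjusted p = 6.96e-06). Col3a1 (2.39 ± 0.08), Acta2 (3.15 ± 0.10) and Mmp2 (1.53 ± 0.08) rose. By edgeR's quasi-likelihood test, Benjamini-Hochberg, the largest adjusted p of the genes valued was 1.04e-18. In all, 5320 genes were higher and 5225 lower, with 1486 and 1225 at least 2-fold.

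**Figure D3:**
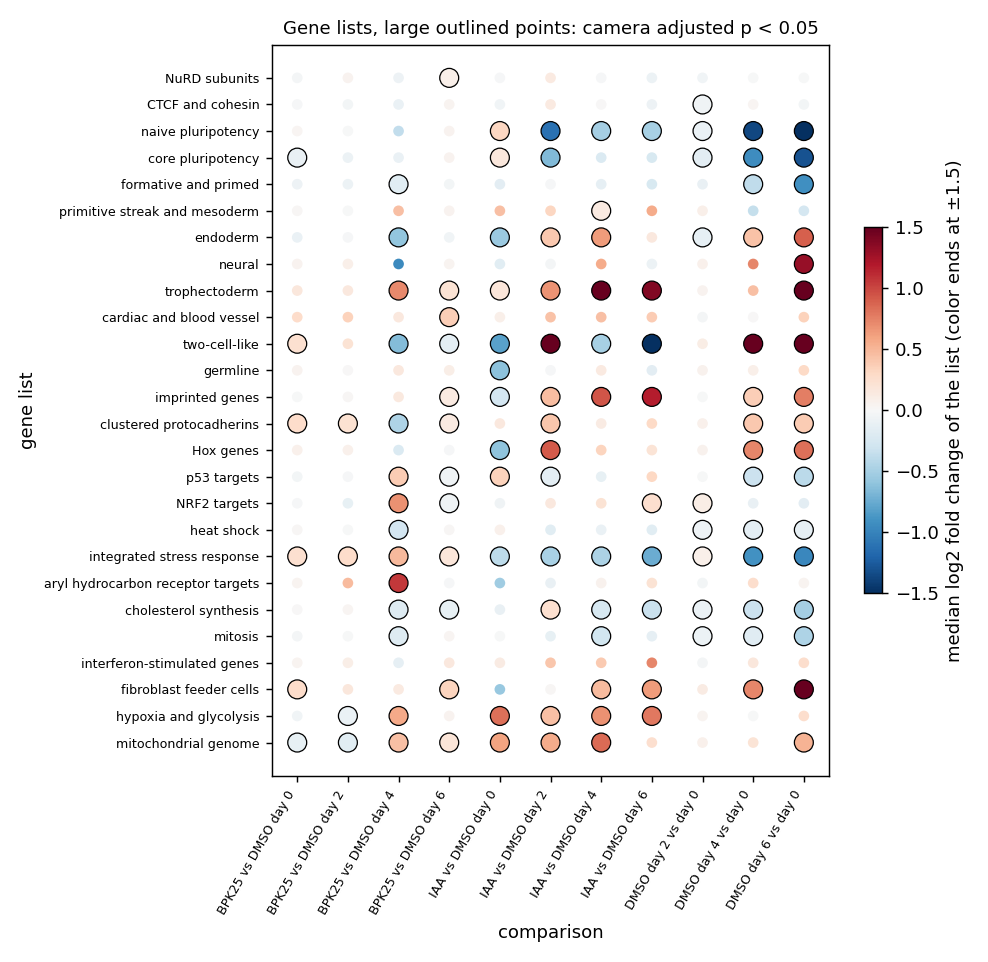
Median log2 fold change of each of the 26 gene lists (vertical, color, ends at 1.5) in each comparison with DMSO and over days in DMSO (horizontal), large outlined points having a camera adjusted p under 0.05. The integrated stress response list is higher in BPK25 at each day and lower in IAA at each day.

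BPK25 and IAA were also compared directly, and 11 of the 26 lists were called at day 0. 16 of the 20 tested integrated stress response genes were higher in BPK25, 2 were lower and 2 did not pass, with 16 up and 2 down adjusted within the list (camera adjusted p = 1.81e-11). For hypoxia and glycolysis genes, 2 of 19 tested were higher in BPK25, 14 were lower and 3 did not pass, with 2 up and 14 down adjusted within the list (camera adjusted p = 3.13e-33). Of 20 tested germline genes, 17 were higher in BPK25, 0 were lower and 3 did not pass, with 18 up and 0 down adjusted within the list (camera adjusted p = 1.49e-09). Mgp (2.46 ± 0.26), Zfp629 (2.37 ± 0.24) and Cyp26a1 (2.17 ± 0.05) were higher in BPK25. Kcnh3 (-5.24 ± 0.34), St8sia1 (-4.45 ± 0.29), Aire (-3.85 ± 0.24) and the POU factor gene Pou2f3 (-3.18 ± 0.28) were lower. No gene given a value here had an adjusted p above 4.53e-11 (edgeR's quasi-likelihood test, Benjamini-Hochberg). In all, 4308 genes were higher and 4025 lower in BPK25.

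At day 2 BPK25 held more pluripotency expression than IAA, and 12 lists were called. Among naive pluripotency genes, 16 of 18 tested were higher in BPK25, 1 was lower and 1 did not pass, with 16 up and 1 down adjusted within the list (camera adjusted p = 1.12e-12). 0 of the 19 tested 2-cell-like genes were higher in BPK25, 17 were lower and 2 did not pass, with 0 up and 18 down adjusted within the list (camera adjusted p = 4.76e-18). For Hox genes, 4 of 34 tested were higher in BPK25, 23 were lower and 7 did not pass, with 4 up and 24 down adjusted within the list (camera adjusted p = 9.34e-08). Lefty1 (4.44 ± 0.08) and Lefty2 (4.79 ± 0.08) were higher in BPK25. Hoxc8 (-4.73 ± 0.21), Meox1 (-4.72 ± 0.18), Aldh1a1 (-4.38 ± 0.28) and the transthyretin gene Ttr (-3.95 ± 0.29) were lower. Gkn1 was 350 times higher in BPK25 (95% exact interval 96.5 to 2.89e+03) and Gkn2 186 times (exact interval 63.4 to 904). Without IAA day 2 replicate 2 Gkn2 was higher by 361 times (exact interval 64.5 to 1.43e+04). With edgeR's quasi-likelihood test, Benjamini-Hochberg, every adjusted p of the genes valued was at most 1.87e-16. In all, 5074 genes were higher and 4932 lower.

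At day 4, 11 lists were called between BPK25 and IAA, some higher and some lower in BPK25. Of 20 tested integrated stress response genes, 19 were higher in BPK25, 1 was lower and 0 did not pass, with 19 up and 1 down adjusted within the list (camera adjusted p = 1.79e-19). Among aryl hydrocarbon receptor targets, 4 of 7 tested were higher in BPK25, 2 were lower and 1 did not pass, with 4 up and 2 down adjusted within the list (camera adjusted p = 4.54e-07). 4 of the 17 tested neural genes were higher in BPK25, 11 were lower and 2 did not pass, with 4 up and 12 down adjusted within the list (camera adjusted p = 0.0438, adjusted p = 0.0953 with an estimated correlation). For hypoxia and glycolysis genes, 4 of 19 tested were higher in BPK25, 13 were lower and 2 did not pass, with 4 up and 13 down adjusted within the list (camera adjusted p = 0.0343, adjusted p = 0.0606 with an estimated correlation). Cyp1a1 was 753 times higher in BPK25 (95% exact interval 257 to 3.65e+03). Without IAA day 4 replicate 2 it was higher by 1.55e+03 times (exact interval 278 to 6.12e+04). Nupr1 (3.31 ± 0.15), Dusp8 (3.27 ± 0.19) and Cavin1 (3.08 ± 0.06) were higher. The mesoderm factor genes Foxc2 (-4.67 ± 0.27) and Foxd2 (-4.59 ± 0.37) and Syt6 (-4.72 ± 0.32) were lower. Nepn was 137 times lower in BPK25 (exact interval 46.7 to 669), or 248 times (exact interval 44.3 to 9.83e+03) and 89 times (exact interval 30.3 to 433) without BPK25 day 4 replicate 1 or 3. For the genes given values, adjusted p reached at most 4.07e-15 (edgeR's quasi-likelihood test, Benjamini-Hochberg). In all, 4729 genes were higher and 4721 lower.

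At day 6, 10 lists were called between BPK25 and IAA. Of 19 tested 2-cell-like genes, 18 were higher in BPK25, 0 were lower and 1 did not pass, with 18 up and 0 down adjusted within the list (camera adjusted p = 8.87e-12). Among imprinted genes, 6 of 26 tested were higher in BPK25, 16 were lower and 4 did not pass, with 6 up and 17 down adjusted within the list (camera adjusted p = 4.71e-23). 7 of the 20 tested fibroblast feeder markers were higher in BPK25, 10 were lower and 3 did not pass, with 7 up and 10 down adjusted within the list (camera adjusted p = 0.000883). The median of the last list was -0.36 but its mean 0.03. Gkn1 (7.91 ± 0.16), Gkn2 (6.88 ± 0.14) and Mucl3 (6.62 ± 0.13) were higher in BPK25. Gstm3 (-4.42 ± 0.33), Aqp1 (-3.99 ± 0.17), Fendrr (-3.81 ± 0.35) and the troponin gene Tnni2 (-3.96 ± 0.31) were lower. Cyp1a1 was 53.5 times higher (95% exact interval 18.0 to 262). Without IAA day 6 replicate 3 it was higher by 111 times (exact interval 19.7 to 4.41e+03). The largest adjusted p among genes valued here was 1.44e-11 (edgeR's quasi-likelihood test, Benjamini-Hochberg). In all, 4820 genes were higher and 5018 lower.

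The gene for CTCF and the genes of NuRD subunits were followed in every comparison. Ctcf rose in BPK25 at day 4 (0.41 ± 0.04) and in IAA at day 2 (0.26 ± 0.04), and fell in IAA at day 6 (-0.13 ± 0.04), a call lost without IAA day 6 replicate 3 (-0.09). It did not pass in the other comparisons with DMSO of the same day. Chd4, which encodes the main remodelling ATPase of NuRD, rose in IAA at days 2 (0.52 ± 0.04) and 6 (0.51 ± 0.04). The methyl-binding domain gene Mbd3 (-0.50 ± 0.04) and the deacetylase gene Hdac1 (-0.98 ± 0.05) fell in IAA at day 6. The histone chaperone gene Rbbp7 rose in IAA at days 2 (1.05 ± 0.04), 4 (0.70 ± 0.04) and 6 (1.03 ± 0.04). Mta2 fell at day 4 in BPK25 (-0.58 ± 0.05) and IAA (-0.66 ± 0.05). Chd5 rose in BPK25 at day 4 (1.32 ± 0.09) and fell over 6 days in DMSO (-2.04 ± 0.09), where Chd3 (0.99 ± 0.06) rose and Mta3 (-0.80 ± 0.04) fell. Genes valued here each had an adjusted p of at most 0.00437 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Transcript levels say nothing here of protein levels, including that of a degron-tagged protein.

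The effect of each treatment differed between days, for 8196 genes (47.1% of those tested) under BPK25 and 12188 (70.1%) under IAA. For BPK25 the smallest p-values belonged to Ccn1, Lama1, Myo7a, Ahnak and Pth1r. Ccn1 had log2 effects of -0.38, -0.37, 4.48 and 0.32 at days 0, 2, 4 and 6, and Lama1 -0.09, -0.13, -1.66 and -0.18. With day 4 left out, an alternative added after seeing the data, 1400 genes differed for BPK25 and 11122 for IAA. For IAA the leading genes were Tdgf1, Cyp26a1, Crabp2, Stra8 and Dsp. Tdgf1 had log2 effects of 1.11, -3.88, 1.42 and 2.24, and Crabp2 -0.48, 4.23, -0.26 and 0.32. Stra8, a retinoic acid-induced gene of meiotic entry, had -1.30, 0.36, -1.39 and -2.63. Across genes, BPK25 effects correlated at 0.217 between days 0 and 2 and at -0.004 to 0.098 between other days. IAA effects correlated at 0.706 between days 4 and 6 and at 0.142 to 0.45 between other days. Genes are not independent replicates. Under BPK25, 26 genes were higher and 14 lower at all 4 days, where independent lists would share 0.389 and 0.467. Under IAA, 899 were higher and 988 lower, against 80.8 and 87.7.

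**Figure D4:**
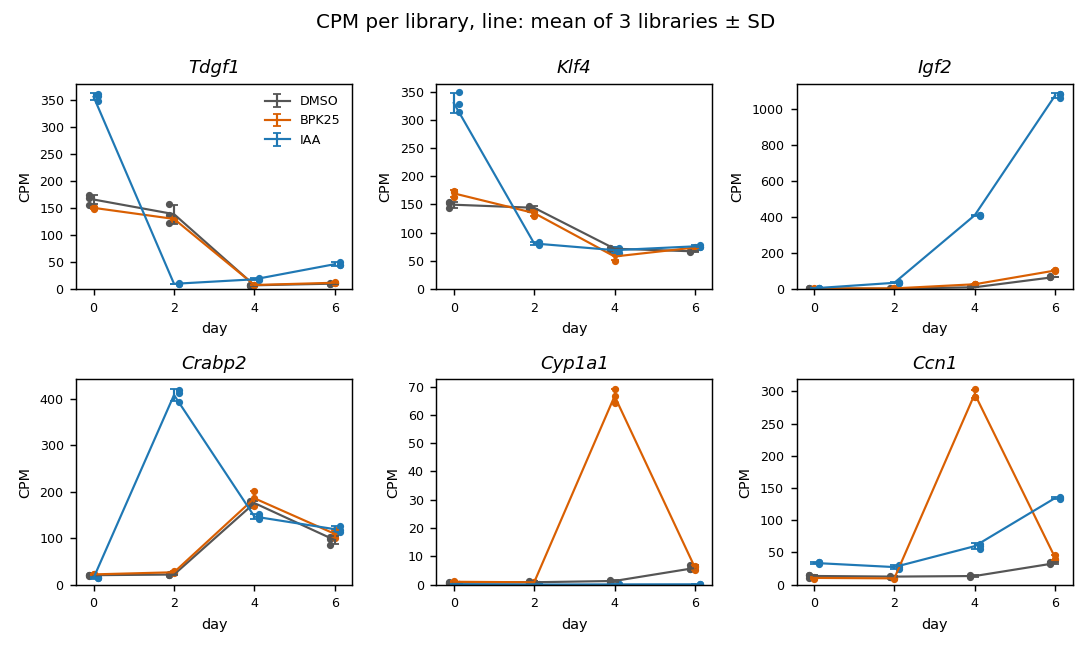
Levels in CPM of 6 genes by day, each point 1 library and each line the mean of 3 libraries ± SD, in DMSO, BPK25 and IAA. Cyp1a1 and Ccn1 peak in BPK25 at day 4 and Crabp2 in IAA at day 2.

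Both treatments were compared with the same DMSO libraries, so their effects share chance values. The correlation across genes of the BPK25 and IAA effects was 0.273, 0.298, 0.418 and 0.323 at days 0, 2, 4 and 6. In 20 simulations of unchanged groups against those controls it was 0.569, 0.555, 0.543 and 0.419. The covariance was 0.0612, 0.088, 0.216 and 0.0807, against 0.0578, 0.0487, 0.0419 and 0.0297 simulated. At day 4, 2259 genes were higher in both and 2509 lower in both, where independent lists would share 1183 and 1207. At day 0 the numbers were 219 and 364 against 123 and 184.5. The 3 control libraries of a day cannot be split, so part of the excess may come from the shared controls. Without DMSO day 0 replicate 2 the correlation at day 0 was 0.399, and with no filter it was 0.473 at day 0 and 0.441 at day 2.

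Positions on GRCm38 of the main genes were as follows. Ctcf (ENSMUSG00000005698.15) lies on chromosome 8, 105636568 to 105682922, plus strand. Chd4 (ENSMUSG00000063870.12) lies on chromosome 6, 125095981 to 125130591, plus strand, Mbd3 (ENSMUSG00000035478.14) on chromosome 10, 80392539 to 80399550, minus strand and Mta2 (ENSMUSG00000071646.9) on chromosome 19, 8941875 to 8952303, plus strand. Cyp1a1 (ENSMUSG00000032315.6) lies on chromosome 9, 57687928 to 57703824, plus strand, Gkn1 (ENSMUSG00000030050.4) on chromosome 6, 87345650 to 87350942, minus strand and Gkn2 (ENSMUSG00000030049.5) on chromosome 6, 87373357 to 87379497, plus strand. Igf2 (ENSMUSG00000048583.16) lies on chromosome 7, 142650766 to 142666816, minus strand, Tdgf1 (ENSMUSG00000032494.12) on chromosome 9, 110939603 to 110946158, minus strand and Ccn1 (ENSMUSG00000028195.4) on chromosome 3, 145646976 to 145649981, minus strand. Crabp2 (ENSMUSG00000004885.5) lies on chromosome 3, 87948666 to 87953376, plus strand and Cyp26a1 (ENSMUSG00000024987.6) on chromosome 19, 37697798 to 37701536, plus strand.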

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

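The tests of a swap and of feeder cells, and all counts of other splits of the libraries, were chosen only after the results they bear on were seen. The day 4 alternative was also added after seeing the data.

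The effect of BPK25 differed between days for 8196 genes in a joint test, led by Ccn1 (adjusted p = 1.9e-35), Lama1 (4.12e-33), Myo7a (1.57e-30), Ahnak (1.64e-30) and Pth1r (2.28e-29) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Myo7a had log2 effects of -0.06, 0.12, -2.71 and -0.37 at days 0, 2, 4 and 6, Ahnak -0.16, 0.01, 1.92 and 0.16, and Pth1r 0.07, -0.09, -2.55 and -0.15. The effect of IAA differed between days for 12188 genes, led by Tdgf1 (adjusted p = 6.29e-40), Cyp26a1 (6.83e-39), Crabp2 (2.25e-38), Stra8 (1.06e-37) and Dsp (9.15e-35) by the same edgeR test. Cyp26a1 had log2 effects of -2.04, 1.47, 0.18 and -0.61, and Dsp 0.03, 2.1, -0.40 and -0.12. Of 40 splits of libraries within days, only the real one called as many genes for each treatment. It called 8009 for BPK25 and 12137 for IAA in the smaller fits used, against 5463 and 4511 at most. This tests chance with no effect at any day (share under 0.05), not an equal effect each day or 1 culture per group.

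BPK25 at day 4 differed from DMSO far more than at days 0, 2 and 6. A swap with another group in the series stays open. IAA at day 2 lay 0.493 from DMSO at day 4 and 0.506 from BPK25 at day 4, which lay 0.608 from that DMSO group. BPK25 at day 6, itself nearest to DMSO at day 6, was at 0.435. BPK25 lay at most 0.274 from DMSO at the other days, but where true BPK25 libraries lie at day 4 is unknown. Depth was argued against, since with every library thinned to the depth of the smallest library 8304 genes were still called at day 4. The numbers at days 0, 2 and 6 were 1084, 1847 and 719. More feeder cells stay open. The collagen sum, 9.98 ± 1.04 CPM against 18.4 ± 1.15 in DMSO (SD, n = 3), cannot decide, as differentiating cells make collagens too. Of 20 fibroblast markers, 8 were higher and 5 lower. A wrong label, a sample from outside the series or a difference in how that culture was handled may still account for it, since all 3 libraries share the group; Gkn1 was under 1 CPM there as in IAA at days 2, 4 and 6, while Cyp1a1 was high as in no IAA group. An effect of the compound that comes and goes is likewise open and untested, and only the 3 libraries of that group bear on it.

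The IAA effect at days 2 and 4 ran along the change over days in DMSO. Across 17394 genes its correlation with the DMSO change from day 0 to day 6 was 0.511 at day 2 and 0.378 at day 4, while that of BPK25 at day 4 was -0.118, so IAA libraries at those days may lie further along the same change; against a DMSO change not sharing their controls, IAA was at 0.0113 at day 6 and -0.181 at day 0. A trend with transcript length was argued against, because with it removed the day 2 value was 0.51. More feeder cells stay open. At day 2, 8 of 20 fibroblast markers were lower and 6 higher. With 4861 of 17394 genes lower this cannot decide. The collagen sum was 18.6 ± 0.79 CPM against 8.73 ± 0.653 in DMSO (SD, n = 3), and 38.7 against 18.4 at day 4. Whether loss of a tagged protein, auxin itself or a clone difference caused the pattern is open: the design does not separate them.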

How the results depend on the processing

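The alternative that leaves out day 4 was chosen only after the results were seen; the others were fixed before the data were examined. No named gene, list or correlation reversed past its threshold under any alternative run, but the direction with more calls turned under some alternative in 10 of 15 comparisons, 8 of them with no filter. It did not for BPK25 at day 6, BPK25 against IAA at days 2 and 6, and DMSO at days 2 and 6. Counts of genes stayed within 1.5 times in 361 refits and left that range in 23. Correlations moved by under 0.1 in 61 refits. Named genes kept their direction and side of the threshold in 11952 refits, fell out in 256 and entered in 37. Lists stayed on their side of the threshold in 2406, passed only in the alternative in 203 and fell out in 43. At this depth and with 3 libraries, for BPK25 at day 0, 36% of genes were recovered at the smallest simulated fold and 100% at 4-fold. These genes had a mean of at least 1 CPM.

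With day 4 left out the BPK25 joint test gave 1400 genes. No other day was left out for comparison, so the cause of the drop was not tested. With no filter, 402 genes were lower and 606 higher in BPK25 at day 0, against 797 and 577, and correlations of the BPK25 and IAA effects were 0.473 and 0.441 at days 0 and 2. DESeq2 gave 330 lower in BPK25 at day 6, and a fit of only the libraries compared gave 379 lower in DMSO at day 2; the cause was not tested. The share of higher calls for BPK25 at day 6 went from 56.6% to 62.5% with RLE and 65.6% with DESeq2. The replicate numbers did not pair libraries: same-numbered deviations correlated at -0.0282 to 0.047 and in 13 of 36 same-numbered pairs of libraries under 2 treatments the own number correlated best. The replicate block moved no count by over 1.5 times (551 genes higher in BPK25 at day 0, against 577).

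Of the 26 lists, the number called went from 6 to 1 for BPK25 at day 0, 4 to 1 at day 2, 14 to 9 at day 4 and, in DMSO at day 2, 9 to 4 with an estimated correlation. With no filter it was 7 for BPK25 at day 2, 16 for IAA at day 6, 17 and 16 for BPK25 against IAA at days 4 and 6. With fry it was 11 and 24 for BPK25 at days 2 and 4, 22, 24, 23 and 24 for IAA at days 0, 2, 4 and 6, and 23, 24, 25 and 24 for BPK25 against IAA; fry does not compare a list with other genes, and the other causes were not tested.

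Leaving out each library in turn gave these lowest and highest numbers, higher then lower genes. BPK25 gave 359 to 445 and 439 to 567 at day 0, 777 to 931 and 921 to 1009 at day 2, 4132 to 4345 and 4209 to 4386 at day 4, 320 to 710 and 224 to 514 at day 6. IAA gave 3315 to 3540 and 3463 to 3700 at day 0, 4371 to 4546 and 4397 to 4591 at day 2, 4064 to 4242 and 4023 to 4183 at day 4, 4940 to 5161 and 4654 to 4878 at day 6. BPK25 against IAA gave 3666 to 3957 and 3594 to 3763 at day 0, 4635 to 4801 and 4560 to 4685 at day 2, 4197 to 4436 and 4271 to 4501 at day 4, 4291 to 4505 and 4622 to 4847 at day 6. DMSO against day 0 gave 124 to 286 and 288 to 668 at day 2, 4026 to 4255 and 3777 to 3960 at day 4, 5212 to 5476 and 4742 to 5149 at day 6. Joint tests gave 7542 to 8174 for BPK25 and 11835 to 12061 for IAA, and correlations 0.244 to 0.399, 0.265 to 0.391, 0.391 to 0.456 and 0.278 to 0.384 at days 0, 2, 4 and 6.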

Other observations

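The counts of other splits of the libraries were chosen only after the results were seen, and the genes of the next 2 paragraphs that other parts do not name were chosen after their values were seen.

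Nodal fell over days in DMSO, with a log2 change of -3.85 ± 0.13 from day 0 to day 6. It was at 36.8 ± 1.08 CPM in DMSO at day 0, 6.33 ± 1.47 at day 4 and 2.46 ± 0.380 at day 6 (SD, n = 3). In IAA at day 2 Nodal stood at 12.5 ± 1.30 CPM against 35.1 ± 1.92 in DMSO, and Lefty1 at 7.61 ± 1.45 against 118 ± 2.55. At day 6 Tdgf1 was at 45.7 ± 3.19 CPM in IAA and 9.76 ± 0.985 in DMSO, while Nodal was lower in IAA by a log2 fold change of -1.41 ± 0.31. The retinoic acid receptor gene Rarb, itself a retinoic acid target, was at 6.34 ± 0.671 CPM in IAA and 17.7 ± 2.69 in DMSO at day 0 (-1.48 ± 0.13), and at 68.2 ± 3.24 and 20.2 ± 1.53 at day 2 (1.75 ± 0.08). The largest adjusted p was 9.1e-05 for these fold changes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

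The gastrokine genes separated BPK25 at day 4 from BPK25 at the other days. Gkn1 was at 17.9 ± 2.61, 24.5 ± 1.38 and 102 ± 4.32 CPM in BPK25 at days 0, 2 and 6 and at 16.4 ± 0.591, 20.9 ± 2.85 and 105 ± 0.597 in DMSO (SD, n = 3). At day 4 BPK25 held 3 counts of it in 3 libraries and DMSO 541. Mucl3 was at 0.653 ± 0.0956 CPM in BPK25 at day 4, against 1.44 ± 0.480 in IAA at day 2 and 13.9 ± 1.80 in DMSO at day 4. Myo7a was at 13.0 ± 0.209 in BPK25 at day 4 and 9.65 ± 0.216 in IAA at day 2, against 85.2 ± 0.654 in DMSO at day 4. Cyp1a1 set BPK25 at day 4 (66.6 ± 2.47 CPM) apart from every IAA group, the highest of which was 0.148 ± 0.170. Another YAP target, Ccn2, was at 50.3 ± 0.889 in BPK25 and 17.6 ± 0.796 in DMSO at day 4.

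Small BPK25 differences at days 0 and 2 may owe something to technical trends. With a trend in transcript length removed, 69.7% of the genes called at day 0 and 84.1% at day 2 were still called the same way. With a GC trend removed the shares were 66% and 66.7%, and with all libraries thinned to 1 depth 72% and 70.6%, which argues against each as the whole cause, while why other calls ended was not tested. The stress response list had medians of 0.255, 0.236 and 0.238 at day 0 against 0.244 uncorrected, and 0.258, 0.282 and 0.276 at day 2 against 0.272, with camera adjusted p-values of 5.39e-15, 2.38e-14 and 4.79e-14 at day 0 and 1.53e-15, 7.95e-15 and 6.16e-14 at day 2. An effect of the compound is an open explanation that only its group bears on.

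For each of the 15 comparisons, the 6 libraries make 10 splits, of which 1, the real one, called as many genes, and 10 are too few for a share under 0.05. For BPK25 the real split called 1313, 1948, 9083 and 1015 genes at days 0, 2, 4 and 6, and the highest other 0, 0, 0 and 1. For IAA the numbers were 7799, 9283, 9080 and 10374, and for BPK25 against IAA 8362, 9963, 9570 and 9684, with 0 as the highest other in each. For DMSO at days 2, 4 and 6 they were 606, 8704 and 10876, with 3, 0 and 0.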
